A study of Mus musculus with 4 samples.

How the data were processed

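Single-cell RNA sequencing was performed on mesenchymal stromal cells (MSCs) of C57BL/6 mice, in 4 libraries with 1 library per group. Per the labels' protocols, femora and tibiae were crushed and treated with collagenase, and cells lacking CD45, TER119 and CD31 and carrying CD140a and CD51 were sorted. Libraries were built with the Chromium 3' chemistry, which reads the 3' ends of transcripts and counts molecules through unique molecular identifiers (UMIs), and were sequenced on a NextSeq 500, per the labels' protocols. Reads were processed with Cell Ranger 3.1.0, and Seurat 3.2.3 is also named, per the submitters' processing notes. The deposited files hold whole UMI counts per gene and barcode for 27998 genes, not normalized and not restricted to cells, so cells were called anew. The genome build and annotation are not given in the sources used here, and no coordinates were used. No cell annotation was used, so all class names were rebuilt.

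The series pairs WT_A1 with NHD13Tg and Control with Abcg2-MDS/AML. With 1 library per group there is no replicate check: a difference between libraries of a pair is a difference between these libraries, with no p-value, and all intervals cover counting error only. Intervals are exact at the 95% level, Poisson for summed counts, Clopper-Pearson binomial for shares, and conditional binomial for ratios. In differences of shares the interval combines those of the shares by squaring and adding. Against a library with 0 counts a fold is a bound, computed with 3 counts over the summed library in its place.

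A barcode was called a cell with at least 500 genes, at most 10% of UMIs from mitochondrially encoded genes, and UMIs at or above the larger of 1000 and the 99th percentile of the 3000 largest barcodes divided by 10. That threshold came to 2740 UMIs in WT_A1, 2436 in NHD13Tg, 4552 in Control and 2061 in Abcg2-MDS/AML. Doublets were scored with Scrublet in scanpy 1.11.5, whose own threshold marked between 0 and 2 cells per library, so the highest scores were removed at a fixed rate of 0.8% per 1000 called cells. Counts were log-normalised in Seurat 5.3.0, with 2000 variable genes and 30 components, integrated across the 4 libraries by canonical correlation and clustered at resolution 0.5.

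A cluster was named "like" a cell type from marker lists written before the data were examined. Genes were ranked by CPM (counts per 1000000 summed counts) in the cluster over CPM in all other cells, with 10 CPM added. A name needed at least 3 markers among the top 50 genes, at least 2 among the top 10 and more there than any other type had. The number 3 was settled after the clusters had been seen. Requiring 4 would have left 1 chondrocyte-like and 1 tenocyte-like cluster unnamed. Clusters left without a name held 23.5% of cells in WT_A1, 14.9% in NHD13Tg, 7.31% in Control and 14.2% in Abcg2-MDS/AML. Because clusters built with MSC and osteolineage markers cannot be used to compare those markers, clustering was repeated without these markers and the main compared lists (206 genes), an alternative added after the data had been seen.

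In MSC-like cells UMIs were summed per library and log2 ratios of CPM were computed with 0.5 added to each count. Genes with at least 20 CPM in 1 library of a pair were considered. A size rule, which is not a test, took genes at least 2-fold apart whose counting interval left out a ratio of 1. A gene was set apart where its CPM in free RNA (barcodes with 1 to 100 UMIs) reached its CPM in the class. For lists written before the data were examined, members with at least 5 CPM counted as measured, members at least 1.5-fold apart with an interval leaving out 1 were counted, and the median log2 ratio was placed among 10000 random lists of equal size matched on mean expression in 20 bins. The main lists were osteolineage commitment and matrix, haematopoietic niche factors, adipogenic genes and the interferon response. Of 32 lists fixed, 7 are described in detail. They were chosen after the values of all lists and their behaviour under the alternatives had been seen, and one reason was that fewer named genes then reversed, so counts of reversed genes cover only these lists and the other named genes.

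Named genes followed a rule fixed at the same time: the 10 largest ratios in each direction per pair, up to 8 per direction past the size rule in both pairs, 2 to 4 members of each described list (highest CPM among those past 1.5-fold), the model genes, the genes of the sort, and for the joint test the 10 lowest adjusted p in each direction. Genes set apart for free RNA, sex-linked and mitochondrially encoded transcripts, symbols of Gm with digits or ending in Rik, and immunoglobulin segments stayed out of the rankings of the pairs. Clone names such as RP24-330M21.1 are not covered by that exclusion, and the ranking of the joint test applied none of it. A gene that the rule takes in the Abcg2 pair is not reported here.

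The only test with residual degrees of freedom takes the models together. Summed counts of the 4 libraries were fitted in edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood) with terms for experiment and for model against control, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. It has 1 residual degree of freedom per gene, and it does not test either model by itself.

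Alternatives were other UMI, gene and mitochondrial limits, doublets kept, no integration, resolution 1, other scaling, low-value filters of 50 CPM or none beyond 3 counts, free RNA subtracted, equal weight per cell, all stromal classes summed and 1 CPM as pseudocount. For the joint test they were DESeq2 1.42.0, its size factors within edgeR, no filter and no experiment term. Added after the data were seen were a minimum of 1000 UMIs in every library, the highest library's threshold in every library, 4 markers for a name, other denominators and free RNA subtracted with the share from either list alone, from the chondrogenic list or at the lower of the upper limits of the first lists. Counting intervals of list medians and correlations across genes came from Poisson redraws centred on the observed value; the centring was introduced after a first look, since redrawn counts carry extra noise.

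The free RNA share of UMIs in MSC-like cells was estimated from the erythroid and neutrophil transcript lists. It came to 17.0% in WT_A1, 25.4% in NHD13Tg, 10.1% in Control and 37.7% in Abcg2-MDS/AML, but these shares are unreliable. Taken from each list alone, after the data had been seen, the erythroid and neutrophil shares were 11.3% and 23.8% in WT_A1, 60.4% and 14.9% in NHD13Tg, 4.85% and 33.1% in Control, and 98.1% (84.1 to 114) and 8.07% (5.41 to 11.6) in Abcg2-MDS/AML. In Abcg2-MDS/AML only 202 UMIs lie behind the share, 81 of them from Mkrn1 and 32 from Fech, which stood above their free RNA level in the class. Because RNA made by the class itself can only raise such a share, the lower of the upper limits from the lists bounds it if free RNA has the same make-up in cells as in empty barcodes, at 12.4% in WT_A1, 15.6% in NHD13Tg, 5.69% in Control and 11.6% in Abcg2-MDS/AML. The chondrogenic list gave 2.55%, 5.36%, 21.3% and 2.42%, above that limit in Control, where 1 cell held 1787 of its 6135 UMIs. In WT_A1 and Control 1 cell held 646 of 805 and 187 of 233 neutrophil list UMIs.

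Each calculation was tested on simulated counts with 200 changed genes. For the pairs these were Poisson counts around the mean of the libraries, with no spread between cells or libraries beyond counting. Real counts can thus give more false calls. For the NHD13 pair, with 5909 genes, the size rule recovered 99% of 3-fold and 100% of 6-fold changes with 1 false call. For the Abcg2 pair, with 6192 genes, it recovered 93% and 100% with 100 false calls. Of 40 unchanged lists, 2 in the NHD13 pair and 0 in the Abcg2 pair fell outside the central 95% of random lists. In the joint test, over 9874 genes, edgeR recovered 5.6% of 2-fold and 58.4% of 4-fold changes.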

Results

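Bone marrow stromal cells were profiled from mouse models of myelodysplastic syndrome (MDS), a group of clonal blood disorders with ineffective blood cell formation. The NHD13Tg library came from mice carrying a Nup98-HoxD13 fusion transgene and was paired with the wild-type library WT_A1. The Abcg2-MDS/AML library was paired with the wild-type library Control. Each group had 1 library, so no difference within a pair has a replicate check. The matrices held 37368880 UMIs in WT_A1, 38763489 in NHD13Tg, 46033790 in Control and 36133716 in Abcg2-MDS/AML. Called cells numbered 4372, 5252, 2872 and 5267 in the same order, with median UMIs per cell of 5745, 5070, 7250 and 4174. Intervals in parentheses are 95% counting intervals and cover counting error only.

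The genes behind the sort and the models were read first. In MSC-like cells Pdgfra, which encodes CD140a, stood at 380, 279, 397 and 345 CPM in WT_A1, NHD13Tg, Control and Abcg2-MDS/AML, and Itgav, which encodes CD51, at 115, 126, 155 and 134 CPM. Ptprc, which encodes the excluded CD45, had 0, 1, 3 and 0 UMIs. Pecam1, which encodes the excluded CD31, had 32.8, 12.8, 10.9 and 15.8 CPM, and Ly6a (Sca-1) 38.8, 58.1, 25.5 and 18.1 CPM. Abcg2, a membrane transporter gene, had 48.9 and 40.7 CPM in WT_A1 and NHD13Tg and 56.4 and 47.5 CPM in Control and Abcg2-MDS/AML. Nup98, a nuclear pore gene, had 59, 163, 16 and 14 UMIs and log2 ratios of -0.10 and -1.46, and Hoxd13 had 0, 4, 0 and 1 UMIs. Tags at the 3' ends in stromal cells check nothing about a gene altered in blood cells. Xist, transcribed from the inactive X chromosome of females and named after its values were seen, had 0.746 and 0.127 CPM in the NHD13 pair and 1059 and 986 CPM in the Abcg2 pair. The Y-linked gene Ddx3y had 415, 1042, 0 and 0 UMIs in WT_A1, NHD13Tg, Control and Abcg2-MDS/AML. The NHD13 pair thus reads as male and the Abcg2 pair as female.

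The first comparison asked how the stromal cell types were represented in each library. MSC-like cells, led by Hp, Adipoq, Esm1, Kitl and Cxcl12, made up 36.5% (35.1 to 38.0) of stromal cells in NHD13Tg and 16.3% (15.0 to 17.6) in WT_A1, a difference of 20.2 percentage points (18.3 to 22.1). Fibroblast-like cells, led by Col14a1, Dpt and Clec3b, formed 32.5% in NHD13Tg and 46.1% in WT_A1. Osteolineage-like cells, the bone-forming lineage, formed 14.0% (13.0 to 15.0) in NHD13Tg and 17.1% (15.8 to 18.4) in WT_A1, a difference of -3.09 points (-4.76 to -1.43). That difference moved to -9.86 with 1000 UMIs in every library and to -1.13 (-2.48 to 0.217) of all cells outside the haematopoietic cluster. With MSC-like cells left out of the stromal cells, 617 of 2804 were osteolineage-like in NHD13Tg and 561 of 2753 in WT_A1, not a smaller part. Different clusters held most of the osteolineage-like class: the cluster led by Alpl, Ibsp and Spp1 held 366 cells in WT_A1 and 233 in NHD13Tg, and the cluster led by Bglap, Car3 and Col1a1 held 175 and 356. The share of cells in unnamed clusters was 23.5% in WT_A1 and 14.9% in NHD13Tg.

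Chondrocyte-like cells dominated the other experiment, with 67.8% (65.8 to 69.7) of stromal cells in Control and 38.7% (37.3 to 40.2) in Abcg2-MDS/AML, against 7.08% in WT_A1. Of these cells, 975 of 1495 in Control and 701 of 1745 in Abcg2-MDS/AML lay in a cluster that would be unnamed if 4 markers were required. MSC-like cells formed 4.13% (3.34 to 5.04) in Control and 7.59% (6.83 to 8.40) in Abcg2-MDS/AML, a difference of 3.46 points (2.27 to 4.60). Osteolineage-like cells formed 9.66% and 5.88%, a difference of -3.78 points (-5.25 to -2.37). Fibroblast-like cells formed 4.17% in Control and 25.2% in Abcg2-MDS/AML, tenocyte-like cells 13.9% and 21.6%, and pericyte-like cells 0.317% and 1.04%. A haematopoietic cluster, with erythroid and neutrophil genes in the lead, held 15.9% of all cells in Control, 0.209% in Abcg2-MDS/AML, 1.26% in WT_A1 and 1.01% in NHD13Tg, although the sort excluded CD45 and TER119. The UMI threshold of Control was the highest, at 4552. With 1000 UMIs in every library Control had 5707 called cells in place of 2872, while the haematopoietic cells of all libraries together numbered 616. Its haematopoietic share was thus lower than 15.9% with that minimum. The MSC-like cells of Control numbered 510 in place of 91. The MSC-like and osteolineage-like differences of the Abcg2 pair then stood at -1.47 and 3.22 points, opposite in sign.

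**Figure D1:**
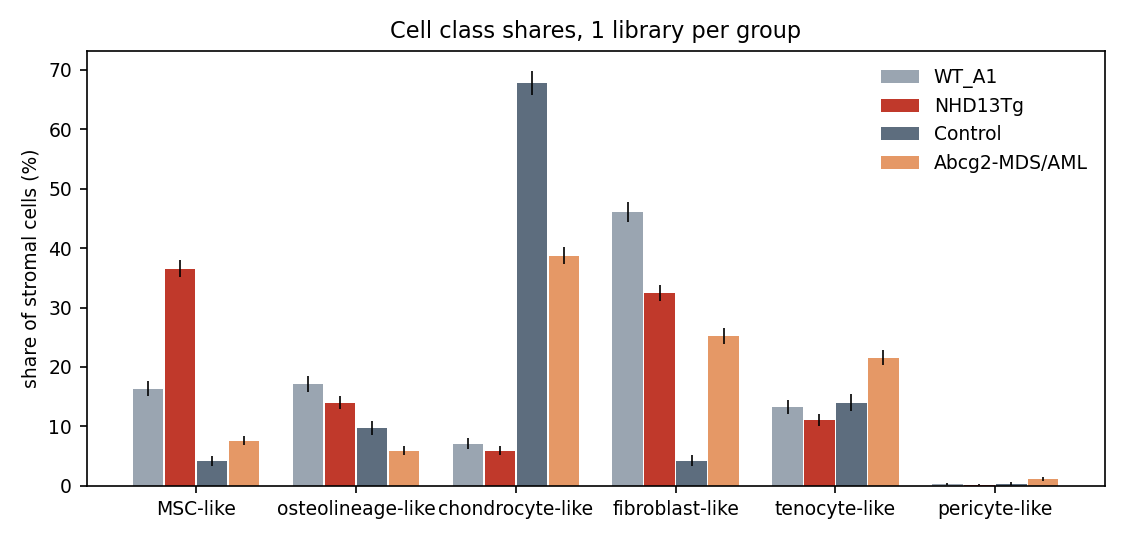
Share of stromal cells (%) in each named class, with 1 bar per library and error bars for the exact 95% binomial interval. MSC-like cells stand at 36.5% in NHD13Tg and 16.3% in WT_A1, and chondrocyte-like cells at 67.8% in Control. Requiring 4 markers for a name would leave 975 of the 1495 chondrocyte-like cells of Control unnamed.

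The next comparison asked how expression in MSC-like cells of NHD13Tg differed from WT_A1, over 1613 and 536 cells and 7867081 and 2679952 summed UMIs. The interferon response list was lower in NHD13Tg, and osteolineage genes as a list lay inside the range of random lists. Of 6129 genes considered, 76 were at least 2-fold higher and 150 at least 2-fold lower in NHD13Tg, of which 18 and 28 had as much free RNA as class RNA. The largest ratio belonged to Saa3, an acute-phase serum amyloid gene (ENSMUSG00000040026), at 359 CPM against 31.7 (11.2-fold; log2 3.49, 3.19 to 3.83). Next came Slc22a8, an organic anion transporter (10.1-fold), Has2, a hyaluronan synthase (8.02-fold), and Lrg1, a secreted glycoprotein of the acute phase (5.79-fold). For Has2, 1 WT_A1 cell held 40% of the 20 UMIs there. Serpina3m (5.37-fold), Barx2 (5.16-fold), Slc10a6 (4.87-fold), Inhbb, an activin subunit (4.60-fold), Mmp13, a collagenase (4.27-fold), and Sfrp2, a secreted Wnt modulator (3.81-fold), completed the list.

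The largest ratios in the lower direction in NHD13Tg were mostly interferon-inducible genes. Ifit1, an interferon-induced antiviral gene, was 7.77-fold lower. The interferon-inducible GTPase genes Tgtp2, Iigp1, Igtp and Irgm1 were 6.52-fold, 5.75-fold, 5.09-fold and 4.46-fold lower, Cxcl10, a chemokine induced by interferon, 4.77-fold, and Rtp4 4.30-fold. The receptor gene Gpr50 was 5.71-fold and the transporter gene Slco1a5 4.33-fold lower. Ccl5, a chemokine, was 13.0-fold lower, but 1 WT_A1 cell held 97.7% of its UMIs there, so this ratio rests on a single cell. On the interferon response list 33 of 40 measured members were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.23, outside the central 95% of random lists (-0.19 to 0.08). Iigp1 stood at 176 CPM in NHD13Tg and 1014 in WT_A1, Cxcl10 at 195 and 933, Irf1 at 307 and 698, and Cxcl9 at 166 and 466. With clusters formed without these genes the median was -1.24. With all stromal classes summed it was -0.18. The same list had medians of 0.04 in osteolineage-like, 0.10 in fibroblast-like, -0.18 in chondrocyte-like and -0.13 in tenocyte-like cells of this pair.

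Haematopoietic niche factors, the signals by which stroma maintains blood-forming cells, had a median of -0.50 in the NHD13 pair, outside the random range (-0.23 to 0.17), with 1 of 19 members higher and 8 lower. Vcam1, an adhesion molecule, stood at 871 CPM in NHD13Tg and 1695 in WT_A1, Igf1 at 129 and 268, Csf1 at 456 and 716, and Spp1 (osteopontin) at 2492 and 4649. With all stromal classes summed the niche median was 0.25, a sum that holds a larger part of MSC-like cells in NHD13Tg. The chemokine Cxcl12 and the stem cell factor Kitl, named after their values were seen, had log2 ratios of -0.09 and 0.11. Osteolineage genes had a median of 0.08, inside the random range (-0.19 to 0.14), with 5 of 30 members higher and 2 lower. Mmp13 (1722 against 403 CPM), Limch1 (643 against 206) and Vdr, the vitamin D receptor (145 against 66.8), were among those higher, and Spp1 among those lower.

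Adipogenic genes had a median of 0.25 in the NHD13 pair, outside the random range (-0.23 to 0.16), with 3 of 19 members higher and 1 lower. Adiponectin (Adipoq) stood at 2246 CPM in NHD13Tg against 1355, Pdzrn4 at 156 against 103, and Angptl4, an inhibitor of lipoprotein lipase, at 164 against 271, while Adipor2, an adiponectin receptor, had a log2 ratio of 0.92. With all stromal classes summed the adipogenic median was 0.64. Hypoxia and glycolysis genes had a median of 0.50, outside the random range (-0.21 to 0.12), with 10 of 26 members higher and 2 lower. The angiogenic factor Vegfa stood at 980 CPM against 553, Ldha at 660 against 434, Gapdh at 572 against 354 and Hif1a at 253 against 147. NF-kB and inflammatory cytokine genes had a median of -0.35 (random range -0.16 to 0.12), with 4 of 32 members higher, among them Saa3 and Serpina3n (867 against 252 CPM), and 13 lower, among them Ccl2 (1929 against 3001) and Nfkbiz (339 against 579). MSC transcription factors and identity genes had a median of -0.23, inside the random range (-0.26 to 0.25), with 1 of 15 members higher and 3 lower. Lepr, the leptin receptor that marks perivascular MSCs, stood at 892 against 1407 CPM, Grem1, a BMP antagonist, at 500 against 1017, Nes at 0.636 against 5.97, and Ebf2 at 15.5 against 10.1.

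The same question was asked of Abcg2-MDS/AML against Control, over 342 and 91 MSC-like cells and 1326074 and 549739 summed UMIs. The interferon response and niche factor lists were lower in Abcg2-MDS/AML, and the NF-kB and inflammatory cytokine list was higher. Of 6605 genes considered, 500 were at least 2-fold higher and 732 at least 2-fold lower, of which 45 and 178 had as much free RNA as class RNA. On simulated Poisson counts of this pair the rule made 100 false calls among 6192 genes. Those counts held no spread between cells or libraries beyond counting, so the real number of false calls can be larger. The MSC-like cells of Abcg2-MDS/AML were less alike the rest of the class: 13 of the 15 MSC markers were at least 2-fold higher there than in other cells of the library, against 15 in each other library, with Foxc1 and Gas6 as the exceptions. Among the 50 leading genes of the class in each library, 4 were markers in Abcg2-MDS/AML, against 10 in WT_A1, 9 in NHD13Tg and 11 in Control. Without integration only 8 of its 342 cells stayed in an MSC-like cluster and 333 lay in unnamed clusters, so the values of this pair rest on the integration.

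Several of the largest ratios were bounds, because Control had 0 counts. Saa3 was at least 31.2-fold higher in Abcg2-MDS/AML (170 CPM), Cxcl2, a neutrophil-attracting chemokine, at least 28.7-fold (157 CPM), Bst1, an ectoenzyme, at least 15.3-fold, Serpina3m at least 9.53-fold and RP24-330M21.1 at least 5.53-fold. Mmp9, a gelatinase, stood at 652 CPM against 2 counts in Control (log2 7.17, 5.63 to 10.53), with UMIs in 47.4% of the MSC-like cells of Abcg2-MDS/AML. Cyp7b1 (5.06, 3.13 to 10.95) and Cd300lg (4.85, 2.92 to 10.75) had 1 count in Control. Serpina3n, a serine protease inhibitor of the acute phase, had a log2 ratio of 4.91.

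In the lower direction, 1 Control cell held 96.8% of the Lyz2 UMIs and 100% of those of Chil3, Tyrobp and Cd52, all genes of myeloid or other blood cells, so these 4 ratios rest on a single cell. Lyz2 had a log2 ratio of -7.26 (-10.63 to -5.70), and Chil3, Tyrobp and Cd52 were at least 22.5-fold, 12.1-fold and 11.3-fold lower. Il1rl1, the interleukin-33 receptor, was at least 18.5-fold lower, with UMIs in 5 Control cells, and Egr4 at least 8.84-fold, with UMIs in 3. Angpt4 and Slco1a4 were at least 10.5-fold lower and Spon2 at least 9.65-fold. Phex, an osteocyte gene, had 28 counts in Control and 1 in Abcg2-MDS/AML (log2 -5.52, -11.43 to -3.48).

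On the interferon response list 32 of 42 measured members were at least 1.5-fold lower in Abcg2-MDS/AML and 2 higher, with a median log2 ratio of -1.56, outside the random range (-0.30 to 0.23). Iigp1 stood at 342 CPM against 2699, Cxcl10 at 1170 against 3674, Irf1 at 343 against 1024 and Cxcl9 at 651 against 1095. With clusters formed without these genes the median was -1.52. Without integration it was -0.50, over 8 cells of Abcg2-MDS/AML, and with all stromal classes summed it was 0.0499, opposite in sign. In the other classes of this pair the list had medians of 0.48 (osteolineage-like), 0.35 (chondrocyte-like), -0.11 (fibroblast-like) and 0.46 (tenocyte-like). The chondrocyte-like and tenocyte-like classes mix clusters in different proportions, 975 and 520 cells in Control against 701 and 1044 in Abcg2-MDS/AML, and 108 and 199 against 654 and 318. Within the 6 single clusters with at least 50 cells in both libraries the medians lay between -0.14 and 0.36.

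**Figure D2:**
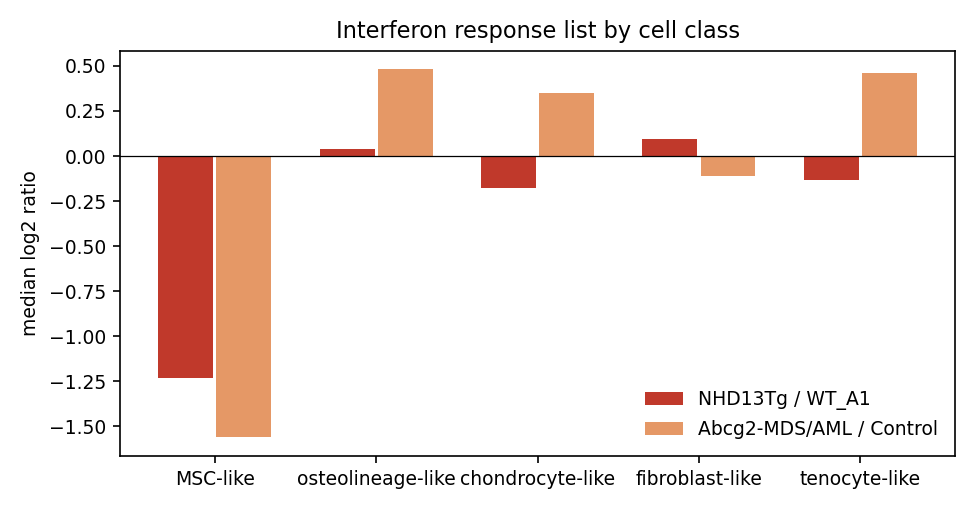
Median log2 ratio of the interferon response list in each cell class, with bars for NHD13Tg over WT_A1 and for Abcg2-MDS/AML over Control. The medians of MSC-like cells stand at -1.23 and -1.56, and those of the other classes lie between -0.18 and 0.48.

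Niche factors had a median of -1.51 in the Abcg2 pair, outside the random range (-0.48 to 0.37), with 3 of 21 members higher and 9 lower, and -1.27 with the member at 0 counts set at its bound. Cxcl12 stood at 1666 CPM in Abcg2-MDS/AML against 15335 (9.20-fold lower), Gas6, a ligand of TAM receptors, at 179 against 2223 (12.4-fold) and Kitl at 909 against 1877 (2.06-fold), while Spp1 stood at 1008 against 588. Cxcl12, Gas6 and Kitl are also among the markers that named the class. With clusters formed without them their log2 ratios were -3.29, -3.66 and -1.13, and the list median was -1.13. Without integration the list median was 0.39, over the 8 cells named above. MSC transcription factors and identity genes had a median of -0.43, inside the random range (-0.51 to 0.43), with 2 of 17 members higher and 6 lower. Grem1 stood at 96.5 CPM against 1335, Ebf3, a transcription factor of marrow reticular cells, at 127 against 489, Ebf1 at 498 against 846, and Pdgfrb at 529 against 300.

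Osteolineage genes had a median of -0.85 in the Abcg2 pair, outside the random range (-0.35 to 0.27), with 5 of 31 members higher and 15 lower. Of these members 14 had as much free RNA as class RNA, and the median of the others was -0.24. With the 2 members at 0 counts at their bounds the median was -0.85, and with clusters formed without the list it was -0.35. The chondrogenic list, of another cell type, moved the same way in these cells, with a median of -3.50, 14 of 16 members lower and 15 of 16 at free RNA levels. With free RNA subtracted by the share of that list the osteolineage median was -0.22, inside the random range above. The matrix genes Sparc and Tnc stood at 2807 against 5155 CPM and 169 against 880, and Cdh11, a cadherin, at 352 against 940. Adipogenic genes had a median of -0.06, inside the random range (-0.37 to 0.34), with 5 of 20 members higher and 7 lower, and -1.07 with members of at least 50 CPM. Adipoq stood at 139 CPM against 3332 (24.0-fold lower), Lpl, lipoprotein lipase, at 302 against 2543 and Cebpb at 1105 against 2323, while Apoe stood at 8713 against 4175. NF-kB and inflammatory cytokine genes had a median of 0.67 (random range -0.30 to 0.25), with 15 of 32 members higher, among them Cxcl1 (4370 against 2008 CPM), Nfkbia (2758 against 1534) and complement C3 (1273 against 240), and 4 lower, among them Socs3 (950 against 2370). With its 5 members at 0 counts set at their bounds the median was 0.52. Hypoxia and glycolysis genes had a median of -0.02, inside the random range (-0.33 to 0.27), with 4 of 26 members higher and 3 lower. Vegfa stood at 243 against 564 CPM, Hk2 at 118 against 371, Ndrg1 at 82.2 against 126 and Hif1a at 281 against 171.

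**Figure D3:**
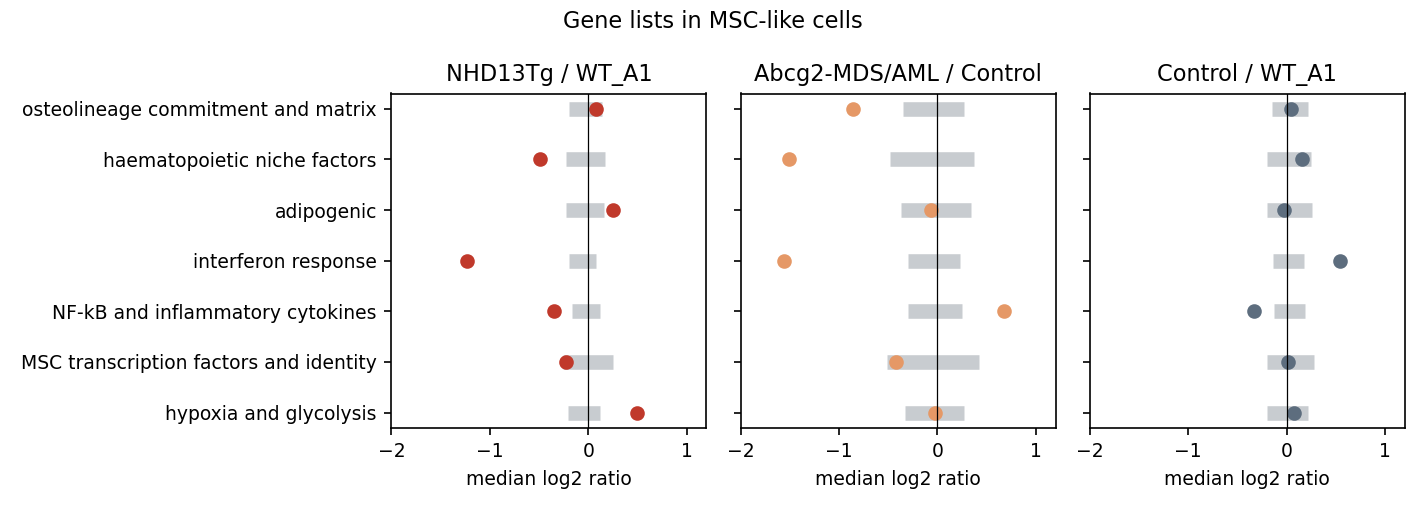
Median log2 ratio of the 7 described gene lists in MSC-like cells (points) for each pair of libraries, with the central 95% of 10000 random lists as grey bars. The interferon response list lies outside the bar in every panel, at -1.23, -1.56 and 0.54.

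The control libraries, both labelled wild type but from different experiments, were compared to see how far they lie apart without a model. Of 6456 genes considered, 289 were at least 2-fold higher and 270 at least 2-fold lower in Control than in WT_A1, more than the NHD13 pair and fewer than the Abcg2 pair. Of these, 129 and 42 had as much free RNA as class RNA. The numbers rest on unlike depth, with 549739 summed UMIs in Control against 2679952 in WT_A1 and 7867081 in NHD13Tg. Thinned to the UMIs of the Abcg2 pair, the NHD13 pair had 411 genes on average. The interferon response list had a median of 0.54, outside the random range (-0.14 to 0.18), with 20 of 42 members higher and 0 lower in Control. NF-kB and inflammatory cytokine genes had a median of -0.33 (random range -0.13 to 0.19), and niche factors, osteolineage and adipogenic genes had medians of 0.16, 0.05 and -0.03, inside their ranges. Chondrogenic genes had a median of 4.55, with 15 of 16 members at free RNA levels. Experiment, library and sex, as read from Xist and Ddx3y, cannot be told apart here.

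The change in the models was then compared gene by gene. Across 5807 genes Pearson's r was 0.165 and Spearman's rho 0.139, and 55.3% of genes had the same sign. Genes are not independent replicates, and the pairs share no library. Among these genes 19 were at least 2-fold higher in both pairs, where independent lists would share 3.61, and 64 were lower in both, where 12.5 would be shared. In opposite directions, 13 were higher in the NHD13 pair and lower in the Abcg2 pair, where 5.89 would be shared, and 13 were lower and higher, where 7.63 would be. Saa3, Serpina3m, Serpina3n, Slc10a6, Inhbb, Ifitm1 (an interferon-induced membrane protein), Hilpda (a lipid droplet protein induced by hypoxia) and Has2 led those higher in both. Ifitm1 had log2 ratios of 1.87 in the NHD13 pair and 3.59 in the Abcg2 pair, and Hilpda 1.44 and 1.51. Ifit1, Iigp1, Igtp, Irgm1, Irgm2, Tmem178, Rtp4 and Tgtp2 led those lower in both. Ifit1 was 7.77-fold lower in the NHD13 pair and 24.2-fold in the Abcg2 pair, Irgm2 3.86-fold and 6.73-fold, and Tmem178 4.05-fold and 6.34-fold.

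The joint test asked which genes differed between model and control in both experiments together. In edgeR's quasi-likelihood test 0 of 9874 genes passed an adjusted p of 0.05, with 478 genes at an unadjusted p under 0.05. These 478 are no larger a part of the genes than that threshold lets through without any difference. DESeq2 called 21 genes, 7 higher and 14 lower, of 4839 with an adjusted p. Without its low-count filter edgeR called 178 genes, and without integration, over 8 cells of Abcg2-MDS/AML, it called 35. The smallest adjusted p in edgeR, 0.0886, was shared by Angptl1, a secreted angiopoietin-like protein (log2 fold change -3.74, SE 0.435), Ifit1 (-3.64, SE 0.451), Iigp1 (-2.70, SE 0.328) and 9930111J21Rik2 (-2.82, SE 0.327). Irgm1, Igtp, Rtp4, Ifit3, Parp14 and Cxcl10 followed on the lower side, with edgeR adjusted p between 0.175 and 0.227. Saa3 had the lowest edgeR adjusted p on the higher side (4.28, SE 0.631, adjusted p = 0.175), followed by the iron-binding acute-phase gene Lcn2 (3.25), Ifitm1 (2.75), Slc10a6, Inhbb, Has2, the protease inhibitor Timp1 (1.85), Hilpda, Serpina3m and Rarres1. The DESeq2 adjusted p of Saa3 was 0.721, and DESeq2 gave none for Lcn2, Slc10a6, Inhbb and Rarres1. Free RNA was as high as class RNA for Lcn2 and Timp1 in both pairs and for Angptl1 and Rarres1 in the NHD13 pair, and 9930111J21Rik2 is an unnamed gene model. In the Abcg2 pair Lcn2 rested on 8 UMIs in Abcg2-MDS/AML against 0 in Control. With clusters formed without the lists its log2 ratio in that pair was -2.91, opposite to 3.07 in the NHD13 pair.

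Among the described lists, 38 of 40 interferon response genes had a negative log2 fold change in the joint test. The edgeR test passed 0 of them over all genes and 30, all lower, when p was adjusted over the list alone. By the same rule 3 NF-kB and inflammatory cytokine genes were higher and 1 lower of 32, and 1 hypoxia and glycolysis gene was higher of 26. Neither of these lists was a main list, and both were picked after the values of all lists had been seen. Their passes over the list alone are thus a description and not a test. Over all genes 0 members of these lists passed in edgeR. DESeq2 passed 6 interferon response genes over all genes, all lower: Iigp1, Ifit1, Irgm1, Igtp, Ifit3 and Cxcl10. In the other lists it passed 1 osteolineage gene (higher), 1 NF-kB and inflammatory cytokine gene (higher) and 1 MSC identity gene (lower). None of the osteolineage, niche factor, adipogenic or MSC identity genes passed in edgeR when adjusted over the list alone, with smallest edgeR adjusted p of 0.146, 0.0558, 0.302 and 0.0975. With simulated counts this test recovered 5.6% of 2-fold and 58.4% of 4-fold changes, so smaller changes were largely out of its reach.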

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

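The results here were picked out because the models went opposite ways, in genes at least 2-fold apart or in list medians outside the central 95% of random lists. Each group had 1 library, so the difference between the models was not tested. Sex, as read from Xist and Ddx3y, also separates the pairs. Only genes named by the rule for the pairs and the 7 described lists enter as genes, while all 32 lists were searched: of the genes considered in both pairs, 13 were higher in the NHD13 pair and lower in the Abcg2 pair, of which 3 are given here, and 13 were lower and higher, of which none was named that way.

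Sfrp2, a secreted Wnt modulator, had a log2 ratio of 1.93 in the NHD13 pair and -3.90 (-7.35 to -2.07) in the Abcg2 pair, with 2 counts in Abcg2-MDS/AML. Barx2, a homeobox gene, had 2.37 and -2.32, with 204 UMIs in NHD13Tg and 6 in Abcg2-MDS/AML. WT_A1 and Control had 13 each, among 2679952 and 549739 summed UMIs, so Barx2 was also higher in Control than in WT_A1. Lrg1, an acute-phase glycoprotein, had 2.53 and -1.55. The NF-kB and inflammatory cytokine list had a median of -0.35 in the NHD13 pair and 0.67 in the Abcg2 pair. The erythroid transcript list had a median of 0.63 and -3.93, with 7 of 8 and 8 of 9 members at free RNA levels, and its median in the Abcg2 pair was -2.69 with the 3 members at 0 counts at their bounds. Control over WT_A1 had medians of -0.33 on the NF-kB list and 0.82 on the erythroid list, outside the random range. A difference between the control libraries can contribute to the opposite signs and cannot be told apart from one between the models. The neutrophil list, also used to estimate free RNA, did not go opposite ways and had medians of -0.53 and -2.89, or -2.83 with its 3 members at 0 counts at their bounds.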

How the results depend on the processing

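The main limits are 1 library per group, the 91 MSC-like cells of Control and the assignment of Abcg2-MDS/AML cells by integration. Alternatives chosen after seeing the data were the common UMI minimums, clustering without markers and lists, 4 markers for a name, the other denominators and free RNA subtracted with the share from either list alone, from the chondrogenic list or at the lower of the upper limits of the first lists, and all those of the MSC-like share. The cause was not tested, except where it follows from how the alternative is built. No paired analysis was possible because each group has 1 library, and the experiment term already pairs the libraries of the joint test. A minimum of 2000 UMIs removed no cell, since every library's threshold was higher.

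In the NHD13 pair the MSC-like difference kept its sign in all 13 alternatives, and moved to 22.7 points with a 20% mitochondrial limit, 25.7 at resolution 1 and 23.5 among MSC-like and osteolineage-like cells. The osteolineage-like difference kept its sign as well, but each denominator tried held the MSC-like cells, whose share was larger in NHD13Tg. Without MSC-like cells, 617 of 2804 stromal cells were osteolineage-like in NHD13Tg and 561 of 2753 in WT_A1, a larger part in NHD13Tg. The osteolineage-like difference moved to -9.42 with 500 UMIs, -5.93 without integration, -8.34 at resolution 1, -9.86 with 1000 UMIs, -5.67 with the highest threshold, -1.13 (-2.48 to 0.217) of all cells outside the haematopoietic cluster and -23.5 among MSC-like and osteolineage-like cells. In the Abcg2 pair the MSC-like difference reversed to -1.07 with 500 UMIs, -3.43 without integration, -1.47 with 1000 UMIs and -0.81 with the highest threshold, and moved to 4.77 with the 20% limit, 0.981 with 4 markers and 26.4 among MSC-like and osteolineage-like cells. The osteolineage-like difference reversed to 3.03 with 500 UMIs, 21.6 without integration and 3.22 with 1000 UMIs, and moved to -15.8 at resolution 1, -10.5 with the highest threshold, -2.37 without markers in clustering, -13.1 with 4 markers and -26.4 among MSC-like and osteolineage-like cells.

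Genes at least 2-fold higher and lower in the NHD13 pair numbered 44 and 65 at 50 CPM, 219 and 636 with no filter, 121 higher with free RNA subtracted and 48 lower with all stromal classes. In the Abcg2 pair they numbered 282 and 91 without integration, 259 and 377 at 50 CPM, 324 and 467 with all stromal classes, and 863 higher with free RNA subtracted. With the free RNA share from the erythroid list alone they numbered 227 and 853 in the NHD13 pair and 1474 and 1889 in the Abcg2 pair, and with that from the neutrophil list alone 186 higher in the NHD13 pair and 902 higher in the Abcg2 pair. Named genes were not computed under these shares. Fewer or more genes enter under the filters by construction.

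With all stromal classes summed, which changes the cells compared, NHD13 medians were 0.25 for niche factors (reversed), 0.64 for adipogenic genes and -0.18 for the interferon response, and Abcg2 medians were -1.22 for osteolineage genes, -0.43 for niche factors and 0.0499 for the interferon response (reversed). Without integration the Abcg2 medians were 0.39 for niche factors (reversed) and -0.50 for the interferon response, over 8 cells. With free RNA subtracted they were -2.50 and -1.28. The Abcg2 osteolineage median was -0.26 with 500 UMIs, -0.32 with 1000 UMIs, -0.35 without the lists in clustering, -0.37 at 50 CPM and -0.30 with no filter. The Abcg2 adipogenic median was -1.07 at 50 CPM. With the free RNA share from the erythroid list alone the osteolineage, niche factor, adipogenic and interferon response medians of the NHD13 pair were -0.0496, -0.17, 0.57 and -0.97, and the osteolineage, adipogenic and interferon response medians of the Abcg2 pair -1.46, -0.67 and -0.66. With that from the neutrophil list alone the interferon response medians were -1.38 and -1.94 and the Abcg2 osteolineage median -0.16. With the share at the lower of their upper limits the NHD13 osteolineage median was -0.0836. With the share from the chondrogenic list it was -0.0748, and the Abcg2 osteolineage and interferon response medians were -0.22 and -1.82.

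Of 2017 single-gene log2 ratios under the alternatives, 1750 stayed inside their counting interval, 239 moved and 28 reversed. Only genes named in the text enter, and the 7 lists whose members are named were chosen after their behaviour here had been seen. With all stromal classes the NHD13 ratios reversed to 0.50 for Ccl2, 0.20 for Csf1, -0.32 for Ebf2, 0.24 for Grem1, 0.48 for Lepr, -0.42 for Ly6a, 0.25 for Spp1 and 0.26 for Vcam1. The Abcg2 ratios reversed to 0.38 for Cebpb, 0.0499 for Cxcl9, 1.48 for Ebf1, 1.502 for Gas6, -0.76 for Has2, -0.67 for Hif1a, 0.56 for Hk2, 0.18 for Irf1, 0.51 for Lpl, 0.57 for Ndrg1, 0.12 for Nup98, 0.32 for Rtp4, 0.13 for Socs3 and -0.51 for Spp1. Joint fold changes reversed to -0.28 for Has2, 0.0060 for Parp14, -1.03 for Rarres1 and -0.39 for Timp1. Without integration Abcg2 ratios reversed to -0.33 for C3, 0.0885 for Egr4, 1.02 for Lyz2, 1.11 for Nup98 and 1.42 for Tgtp2. With free RNA subtracted Spp1 reversed to -9.34.

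Pearson's r was 0.199 with 500 UMIs, 0.189 with 1000 UMIs, 0.0689 without integration, 0.0677 with no filter, 0.266 with all stromal classes, and 0.357 and 0.243 with the free RNA share from the erythroid and the neutrophil list alone and 0.143 with that at the lower of their upper limits. The joint test called 21 genes in DESeq2, 178 with no filter and 35 without integration, and 0 with its other alternatives.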

Other observations

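Of the explanations weighed here, 3 were chosen only after their result had been seen: the whole-library test for the number of genes and both tests of the MSC-like share. The free RNA shares from single lists and at the lower of their upper limits, and the medians in single clusters, were also computed only then. Lists beyond those described above also stood outside the random range, besides the chondrogenic, erythroid and neutrophil lists treated elsewhere. In the NHD13 pair heat shock genes had a median log2 ratio of -0.38, with 5 of 17 members lower and 0 higher in NHD13Tg, and unfolded protein response genes -0.29, with 7 of 24 lower and 1 higher. Neither was limited to MSC-like cells: heat shock genes had medians of -0.48 in osteolineage-like, -0.38 in fibroblast-like, -0.44 in tenocyte-like and -0.15 in chondrocyte-like cells, the last inside the random range, and unfolded protein response genes -0.40, -0.32, -0.31 and -0.30. Osteoclast regulators had a median of -0.64 in that pair, with 4 of 7 members lower and 1 higher, antigen presentation genes -0.27, oxidative phosphorylation genes 0.13 with 39 of 42 members at free RNA levels, and B lineage transcripts 1.94 over 2 members, both at free RNA levels. Control over WT_A1 also lay below the random range for heat shock genes (-0.27), osteoclast regulators (-0.39) and antigen presentation genes (-0.37). Lower values on those lists were thus not particular to NHD13Tg. For unfolded protein response genes the control median was -0.13, inside the range. In the Abcg2 pair immediate early genes, which also respond to tissue dissociation, had a median of -0.59, with 14 of 26 members lower and 2 higher, p53 and senescence genes 0.40, with 7 of 23 higher and 1 lower, and Wnt pathway genes -0.53, with 9 of 23 lower and 0 higher. Ribosomal protein genes had medians of 0.32 and 0.62, but 82 of 83 members were at free RNA levels in each pair.

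Inflammatory genes in the Abcg2 pair were not limited to MSC-like cells. The NF-kB and inflammatory cytokine list had medians of 1.14 in osteolineage-like, 0.56 in fibroblast-like, 0.46 in tenocyte-like and 0.37 in chondrocyte-like cells. In the same classes of the NHD13 pair the medians were 0.21, 0.30, -0.01 and 0.04. In the Abcg2 pair these classes mix clusters in different proportions in the libraries, and within 6 single clusters the medians lay between 0.0196 and 0.90. Hypoxia and glycolysis genes had a median of 0.50 in MSC-like cells of the NHD13 pair and between -0.13 and 0.16 in its other classes.

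The interferon response list was lower in the MSC-like cells of both model libraries. Leaving out the tenth of cells with the largest list share left at least 98.2% of the median in each pair, which argues against a few interferon-high cells, and the lowest median in any other class was -0.177, or -0.38 in any single cluster, which argues against a difference of the whole library. Subtracting free RNA left at least 82.4% with the share from both lists and at least 98.4% with the share at the lower of their upper limits, which argues against free RNA. With the erythroid list alone the medians were -0.97 in the NHD13 pair and -0.66 in the Abcg2 pair, with the neutrophil list alone -1.38 and -1.94, and with the chondrogenic list alone -1.19 and -1.82, but the erythroid share of 98.1% in Abcg2-MDS/AML lies above the upper limit of 11.6% from the neutrophil list. A lower interferon response in MSC-like cells of MDS mice stays a hypothesis, and higher interferon activity in the control animals, by housing, infection or sort, was not tested and stays open too, since the control libraries themselves lie 0.54 apart. In the Abcg2 pair a difference in cell identity stays open as well. Without integration 333 of the 342 Abcg2-MDS/AML cells lay in unnamed clusters, and the clustering without the list genes still used integration.

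More genes were 2-fold apart in the Abcg2 pair (1232) than in the NHD13 pair (226). Thinning the NHD13 pair to the UMIs of the Abcg2 pair raised its mean to 411 genes over 20 draws. This argues against lower depth as the whole cause. It cannot decide on few MSC-like cells in Control, because the thinned sums still averaged over 1613 and 536 cells. Subtracting free RNA gave 1646 genes in the Abcg2 pair. With the erythroid, neutrophil and chondrogenic shares it gave 3363, 1790 and 1538, and at the lower of their upper limits 1320. In the NHD13 pair the number rose too, to 323 with the share from both lists. The subtraction cannot decide on free RNA, because it raised the number under every share, with intervals taken from the reduced counts. Without it, 1009 genes of the Abcg2 pair were not at free RNA levels, against 180 in the NHD13 pair. That argues against free RNA for those genes. Of those 1009 genes, 33.2% also lay 1.5-fold apart in the same direction in the other stromal classes, against 26.1% of the 180. That is too few to make the same genes differ across the library and too many to exclude it. The classes also mix in different proportions. The larger number was not particular to MSC-like cells, at cell numbers that were not matched. Osteolineage-like cells had 408 genes higher and 561 lower in the Abcg2 pair, against 72 and 94 in the NHD13 pair. Chondrocyte-like cells had 207 and 576 against 56 and 106, fibroblast-like 423 and 1048 against 9 and 41, and tenocyte-like 426 and 711 against 30 and 69. With minimums of 500 and of 1000 UMIs in every library, Control had 566 and 510 MSC-like cells in place of 91. The numbers of genes higher and lower then stayed within 1.5-fold of 500 and 732 in the Abcg2 pair. In the NHD13 pair they stayed within 1.5-fold of 76 and 150. This argues against the few MSC-like cells of Control as the whole cause, though the minimum of 1000 UMIs was added after the data were seen. The cell identity under integration and the biology of the model stay open.

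MSC-like cells held a larger share of stromal cells in NHD13Tg than in WT_A1. With the same UMI minimum in all libraries the shares were 33.1% and 13.6%, a ratio of 2.43, which argues against the different minimums. The ratio of MSC-like to osteolineage-like and chondrocyte-like cells was 2.72 times as high in NHD13Tg (2.37 to 3.13), which argues against a mere lack of soft-tissue cells in that sort. Differences in digestion or gating were not tested, and a larger MSC compartment in NHD13Tg is a hypothesis.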
